A study of Mus musculus with 4 samples.

How the data were processed

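The data were RNA sequencing profiles of mouse subcutaneous white adipose tissue from 4 samples, 2 labelled as miR-203 inhibitor and 2 as negative control, each a pool of RNA from 3 animals. Per the labels' protocols, tissue was flash frozen, RNA was extracted with Trizol, and libraries were built from total RNA with a directional NEBNext kit. Per the submitters' processing notes, the tools were TopHat, TopHat2 2.0.11 and Cufflinks 2.1.1 and the genome build was mm10. The settings of these tools, the annotation and whether fragments were assigned by strand are not given in the sources used here. The authors' deposited table gives FPKM values per gene, per the file headers, for 21899 rows with 21849 distinct identifiers. A set of 40 identifiers took 90 rows, and rows were kept apart. An FPKM value is divided by transcript length and by the fragments of its library, so a few abundant transcripts can lower the values of all others, and no read counts can be had from it. Absolute depth is therefore unknown. The relative depth came from the smallest steps between values of genes under 0.3 FPKM. Values at exactly 0 in all samples were in 5341 rows.

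Samples were grouped by their titles. The values were taken as log2(FPKM + 1), and 12345 rows with a mean of at least 1 FPKM over the 4 samples were tested. Inhibitor and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors are the moderated ones of limma, with 5.29 total degrees of freedom, of which 2 are residual. Gene lists were tested with camera, which compares a list with all other genes, at its preset inter-gene correlation of 0.01, with adjustment over the 26 lists of at least 5 measured rows, out of 27 lists. With the correlation estimated from the 4 libraries 0 of the 26 lists passed, against 16 with the preset value (6 higher, 10 lower). The smallest adjusted p was then 0.268, and 3 lists had an unadjusted p under 0.05. In that form camera rests on the 2 residual degrees of freedom, so few lists could pass whatever their correlation. The thermogenic list had an estimated correlation of 0.0104, near the preset 0.01, yet its unadjusted camera p went from 3.24e-18 to 0.0130. For that list the loss therefore does not show that correlated genes had made the call. Estimates of the lists ranged from -0.052 to 0.92, and were 0.75 for type I interferon genes and 0.67 for lipogenesis. Where the estimate is well above 0.01, the preset value can make p too small, so the loss may come in part from correlation. The fry test, which asks whether a list's genes move 1 way on balance, passed 6 lists.

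The tests, the samples, the filter, the pseudocount, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names up to 12 genes per direction with the smallest p among those past the threshold with separate groups and at least a 1.5-fold change. It always names a fixed set that includes Ucp1, Ppargc1a, Cidea, Prdm16, Ifng, Ifngr1, Ifngr2, Jak1, Lyn, Tnf, Adipoq and Lep. It also names up to 4 members with the smallest p from each list described. Some genes that the rule covers are left out of the text. Fisher's exact test on the site was chosen later. Any other gene is named because its values were seen. The lists were thermogenic, respiratory chain, fatty acid oxidation, lipogenesis, adipocyte, interferon gamma response, type I interferon response, interferon gamma signalling, MHC class II, inflammation, macrophage, T and NK cell, B cell and lymph node, granulocyte with mast cell and eosinophil, stromal and matrix, endothelial, smooth muscle and pericyte, skeletal muscle, epithelial and mammary, nerve and Schwann cell, erythroid, cell cycle, immediate early and heat shock, circadian, cAMP and PKA, insulin and glucose, and reported miR-203 targets. Gene families in the closing section were chosen after the data were seen.

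Identifiers matched the GENCODE M21 annotation of GRCm38 for 21647 of the 21849, and coordinates come from it. For the site analysis the longest annotated 3' untranslated region of each gene was searched, and 163 tested genes without one were not searched. The interval of the difference came from 2000 bootstrap resamples of genes, which are not independent replicates.

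The pipeline was tested on 10 simulated tables of 12345 genes with the means and spread of the real libraries, in which 200 genes were changed. It recovered 34.4% of genes changed by a log2 of 1, 72% of those changed by 2 and 89% of those changed by 3, but 3.40% of those changed 1.5-fold, and 3.02% of the calls were false. A list shifted by a log2 of 0.5 was called in 10 of 10 tables and other lists in 0 of 250 tests. Genes were drawn independently in these tables, whereas the correlation estimated in the data ranged from -0.052 to 0.92 between lists. The 0 of 250 therefore does not show how often camera would falsely call a list of correlated genes. Given the recovery of single genes, a change that did not pass is open, above all one under 2-fold.

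Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling to a common sum, rescaling by the upper quartile, quantile normalization, a replicate block, leaving out each library, eBayes without a trend or with the robust option, a threshold of 0.1 and other list tests. The site analysis was also run on the 8-base site alone, and with the trend on 3' UTR length and GC content removed from the values. That last form kept all searched genes and drew no matched set, and its camera test had no trend in the variance. Added after the data were seen were a table without mitochondrially encoded genes and one with the trend on transcript length and GC content removed. The latter was fitted and tested without a trend in the variance, so its counts also carry that change. Python with numpy 2.4.6 and pandas 2.3.3 was used for the tables and figures.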

Results

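RNA sequencing was used to profile subcutaneous white adipose tissue of mice in 2 groups, 1 labelled with an inhibitor of miR-203 and 1 labelled as a negative control. miR-203 is a microRNA, a short RNA that pairs with sites in the 3' untranslated regions of messenger RNAs and lowers their output, and an inhibitor is designed to relieve its targets. The series title places miR-203 between cyclic AMP and interferon gamma in the browning of white fat, the appearance of heat-producing, Ucp1-expressing adipocytes, and in glucose tolerance. Each group had 2 libraries, and each library was made from the pooled RNA of 3 animals, so 6 animals stood behind each group mean. The spread between libraries is therefore a spread between pools. Dose, route and duration of the treatment are not given in the sources used here, and the level of miR-203 itself was not analysed here.

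The expression table held 21899 rows of protein-coding genes with FPKM values, which are fragment numbers scaled to transcript length and library size. Control 1 had 15587 rows above 0, control 2 had 15373, inhibitor 1 had 15487 and inhibitor 2 had 15394. The absolute sequencing depth is unknown. From the most common ratio of low values, the depth relative to control 1 was 1.05 in control 2, 0.925 in inhibitor 1 and 0.903 in inhibitor 2. Replicate libraries correlated at Pearson's r = 0.975 for the controls and 0.986 for the inhibitor libraries, taken across genes, which are not independent replicates. The 13 genes encoded in mitochondrial DNA took 14.4% and 17.5% of the FPKM total in the controls and 10.2% and 12.1% in the inhibitor libraries. The first principal component, with 56.1% of the variance, separated the inhibitor libraries from the controls, and the second, with 29.1%, separated control 1 from control 2.

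The first comparison asked which genes differed between inhibitor and control tissue. Most genes induced by interferons were higher in the inhibitor libraries at an adjusted p under 0.05. They were 26 of 27 on the type I list and 30 of 38 on the interferon gamma list. Of 25 genes of heat-producing fat 8 were lower at that threshold, and 24 had negative log2 fold changes. These 3 lists lost their calls in the camera test with an estimated correlation, which rests on 2 residual degrees of freedom (adjusted p = 0.271, 0.268 and 0.268). Of 12345 genes with a mean of at least 1 FPKM, 397 were higher and 33 lower at an adjusted p under 0.05 with limma, which is 3.48% of the genes tested. The genes that rose had a median log2 fold change of 1.08, with a highest value of 4.01, and those that fell had a median of -0.71, with a lowest value of -2.05. All fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes. At least 2-fold higher, with both inhibitor values above both control values, were 298 genes, of which 223 passed the test. At least 2-fold lower, with the values separated the other way, were 26 genes, of which 8 passed. Separation arises by chance in 33.3% of unchanged genes and was seen in 52.2% of the genes tested. Quantile normalization moved the calls to 326 higher and 92 lower, so that 78.0% of the called genes were higher, against 92.3% without it. Calls over all genes ended without inhibitor 1 and without inhibitor 2, and so did every count of list members past that threshold. Each of those fits took its residual spread from the controls alone. Differences between the controls had an SD of 0.406 on the log2 scale, against 0.298 between the inhibitor libraries. The loss therefore does not show that the calls rested on 1 inhibitor library. Counts with p adjusted over the list alone did not all end: without inhibitor 1 and without inhibitor 2 they were 26 and 26 for type I interferon genes, 35 and 34 for interferon gamma targets and 15 and 14 for thermogenic genes. The medians of these 3 lists stayed at 1.96 and 1.81, 1.33 and 1.19, and -0.81 and -0.82. Limma called 687 higher and 98 lower without control 1 and 400 higher and 61 lower without control 2.

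**Figure D1:**
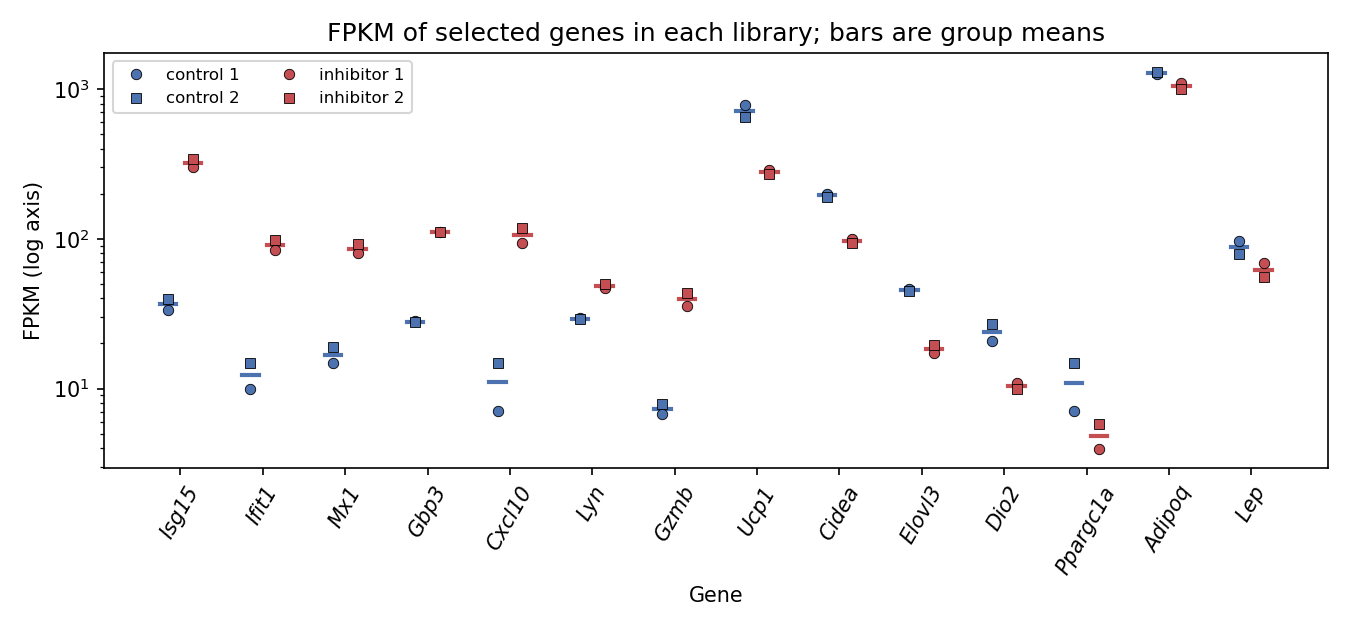
FPKM values of 14 genes in each library on a log axis, with control libraries in blue, inhibitor libraries in red, circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). Isg15 rose from a mean of 36.7 to 323 FPKM and Ucp1 fell from 715 to 279 FPKM.

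Genes induced by type I interferons, which drive the antiviral program, rose almost as a block. Of 27 measured members of this list 26 rose, also with p adjusted over the list alone, and the list median was 3.73-fold higher, a log2 fold change of 1.90. Isg15, which encodes a ubiquitin-like protein that is attached to other proteins in the antiviral response, went from 36.7 ± 4.53 to 323 ± 28.0 FPKM (SD, n = 2), a log2 fold change of 3.10 ± 0.12 (SE, adjusted p = 0.00812). It lies on chromosome 4 at 156199424 to 156200818 on the minus strand of GRCm38. Usp18, the protease that removes ISG15 from proteins, rose from 18.3 ± 2.28 to 84.0 ± 2.33 FPKM, and Mx1, an antiviral GTPase, rose from 16.8 ± 2.92 to 86.0 ± 8.10 FPKM. Trim30a rose from 24.8 to 81.3 FPKM, a log2 fold change of 1.67 ± 0.10. Ifi27l2a was the exception, at 3427 ± 196 FPKM in the controls and 3642 ± 204 in the inhibitor libraries (adjusted p = 0.700). The camera test over the list gave an adjusted p of 1.50e-28, and adjusted p = 0.271 with an estimated correlation.

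Genes listed as targets of interferon gamma, the cytokine named in the title, rose with them. Their rise does not show which interferon acted, since no test here separated a response to interferon gamma from one to type I interferons. Of 38 measured rows of the interferon gamma response list 30 rose, or 36 with p adjusted over the list alone, and the list median was 2.40-fold higher, a log2 fold change of 1.26. Gbp3, on chromosome 3 at 142560026 to 142573209, and Gbp2 encode guanylate-binding GTPases that act against intracellular pathogens. Gbp3 rose from 27.9 ± 0.339 to 110.2 ± 0.00212 FPKM, a log2 fold change of 1.94 ± 0.08 (adjusted p = 0.00812), and Gbp2 rose from 45.7 ± 3.90 to 145.7 ± 1.00 FPKM. Gbp6 rose from 19.0 to 71.1 FPKM in one of its rows. Cd74 (adjusted p = 0.857) and Ciita (adjusted p = 0.850), which serve antigen presentation by MHC class II, did not pass. Camera gave an adjusted p of 4.30e-29 for the list, and adjusted p = 0.268 with an estimated correlation. The 2 lists hold near-identical Gbp, Ifit, Oas and Tgtp genes, and Gbp6 has overlapping rows, so the share of reads of each of these genes is uncertain.

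Among the 12 genes with the smallest p that rose, Isg15, Usp18, Trim30a, Gbp2 and Gbp3 belong to those lists. Ccl4, a chemokine for T and natural killer (NK) cells and monocytes, rose from 3.99 ± 0.469 to 29.1 ± 2.85 FPKM. Lgals9, which encodes galectin-9, rose from 79.8 ± 2.71 to 204.4 ± 5.90 FPKM. Apol9b, Phf11a and Ifit3b had log2 fold changes of 2.42, 2.42 and 2.65, and Pydc4 and Mndal, from a cluster of DNA sensor genes on chromosome 1, had 1.75 and 1.40. These 5 genes have near-identical neighbours, and Mndal overlaps Ifi211 and Ifi203 on the same strand, so their separate values are uncertain.

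The signalling path of interferon gamma was examined next, since the title names it, with genes of the interleukin 12 receptor included. Of 21 measured genes of this path 5 rose and 0 fell, or 13 and 0 with p adjusted over the list alone, which became 5 and 0 without inhibitor 2. Lyn, a kinase of the Src family on chromosome 4 at 3678115 to 3813122, rose from 29.3 ± 0.370 to 48.4 ± 1.76 FPKM, a log2 fold change of 0.71 ± 0.09 (adjusted p = 0.0222). Socs1, a feedback inhibitor of the receptor, rose from 4.42 to 15.9 FPKM, and Il12rb1, a subunit of the interleukin 12 receptor, rose by 1.03 on the log2 scale. The receptor and its kinase did not pass: Ifngr1 had a log2 fold change of 0.15 ± 0.09 (adjusted p = 0.406), Ifngr2 0.34 ± 0.11 (adjusted p = 0.185) and Jak1 0.25 ± 0.12 (adjusted p = 0.345). Ifng itself, on chromosome 10 at 118441046 to 118445892, was below the filter, with 0.242 and 0.230 FPKM in the controls and 0.392 and 1.35 FPKM in inhibitor 1 and inhibitor 2, so it was not tested. The list median was 1.47-fold higher, with a camera adjusted p of 1.22e-08, and adjusted p = 0.271 with an estimated correlation.

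Some chemokines and cytokines of inflammation rose. Of 21 measured members of the inflammation list 9 rose and 0 fell, or 12 and 0 with p adjusted over the list alone. Beside Ccl4, the neutrophil chemokines Cxcl1 and Cxcl2 rose from 5.85 to 22.1 FPKM and from 2.19 to 11.2 FPKM, and the monocyte chemokine Ccl7 rose from 49.3 to 188.0 FPKM. Tnf had 2.20 ± 0.422 FPKM in the controls and 3.66 ± 0.725 in the inhibitor libraries, with a log2 fold change of 0.54 ± 0.20 (adjusted p = 0.243). The median of these genes was 1.82-fold higher, with a camera adjusted p of 8.15e-07, and adjusted p = 0.271 with an estimated correlation. Genes of immediate stress responses gave 3 higher of 18, or 5 with p adjusted over the list alone and 1 of these without inhibitor 2. The 3 were Atf3, Jun and Junb, with Atf3 at 8.63 and 29.2 FPKM, while Fos had a log2 fold change of 0.94 (adjusted p = 0.0711). The median of that list was 0.25, and 0.38 without inhibitor 1 and 0.58 with 5 genes higher without control 1, with a camera adjusted p of 0.00334, and adjusted p = 0.338 with an estimated correlation. Jun did not pass without control 2.

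Macrophage markers were mixed. Of 23 measured, 3 rose and 1 fell, or 9 and 3 with p adjusted over the list alone, which became 3 and 2 without inhibitor 2 and 10 and 1 without control 2. Cd68, a lysosomal protein, rose from 139.4 to 229.8 FPKM, and Fcgr1, a high-affinity receptor for IgG, rose from 44.1 ± 16.3 to 161.7 ± 30.7 FPKM. Gpnmb rose from 17.9 to 33.2 FPKM, and Cd163, the scavenger receptor for haemoglobin, fell by 0.68 ± 0.11 on the log2 scale (adjusted p = 0.0389). The list as a whole lay near the threshold (median log2 fold change 0.33, camera adjusted p = 0.0604), and its call depended on the processing. Without control 2 the list passed (adjusted p = 0.00768), with 6 genes higher and 0 lower and no call for Cd163, and without inhibitor 2 it passed at an adjusted p of 0.0449. It also passed with a replicate block (0.0254), quantile normalization (0.0216), upper quartile scaling (0.0450) and no filter (0.0369), and not with an estimated correlation (0.338).

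Some genes of T cells and natural killer cells rose. Of 24 measured T and NK cell markers 6 rose and 0 fell, or 9 and 0 with p adjusted over the list alone. Gzmb, a protease that cytotoxic cells deliver into their targets, rose from 7.31 ± 0.821 to 39.7 ± 5.62 FPKM, a log2 fold change of 2.29 ± 0.15 (adjusted p = 0.00812). Gzma rose from 20.4 to 71.1 FPKM, Prf1, which encodes the pore-forming perforin, from 3.28 to 8.67 FPKM, and Klrk1, an activating receptor, from 13.0 to 33.3 FPKM. The list median was 1.88-fold higher, with a camera adjusted p of 1.50e-06, and adjusted p = 0.307 with an estimated correlation. Without control 2 the median log2 fold change went from 0.91 to 0.19 with 7 genes higher, and without control 1 it went to 1.37 with 17 genes higher, or 22 with p adjusted over the list alone.

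Control 2 had low values of most B cell and lymph node genes. Ccl21a, a chemokine of lymph nodes, had 127.0 FPKM in control 1, 0.237 in control 2, and 47.8 and 74.4 in inhibitor 1 and inhibitor 2. Glycam1, made by lymph node vessels, had 49.1 FPKM in control 1, 0.295 in control 2, and 28.6 and 33.8 in the inhibitor libraries. Of 18 measured markers in this list 0 passed, here and with p adjusted over the list alone, including Cxcl13, another lymph node chemokine, which had 60.3 FPKM in control 1 and 58.2 in control 2 and so did not share the low values (adjusted p = 0.645). Limma gave 0 of them an unadjusted p under 0.05 (camera adjusted p = 0.543). Their median of 0.75 became 2.38 without control 1, with 17 called higher (camera adjusted p = 7.44e-17), and -1.09 without control 2, with 8 called lower, or 14 with p adjusted over the list alone (camera adjusted p = 1.84e-13). Of 12 MHC class II genes Ctss, a lysosomal protease, was the 1 that rose, from 384.0 to 853.2 FPKM (camera adjusted p = 0.811). H2-DMb2 had 40.3 FPKM in control 1, 3.17 in control 2 and 19.1 in both inhibitor libraries. Its log2 fold change was 0.61 (adjusted p = 0.786), and -1.04 without control 2 (adjusted p = 0.0152). H2-Oa had 0.43 and H2-DMb1 had 0.14, neither past the threshold, and -0.58 and -0.02 without control 2. The class II median of 0.14 became 0.43 without control 1, with 5 called higher (camera adjusted p = 1.62e-05), -0.34 without control 2, with 2 called lower, or 6 with p adjusted over the list alone (camera adjusted p = 0.0001), and 0.08 without inhibitor 1, where camera's direction was down.

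**Figure D2:**
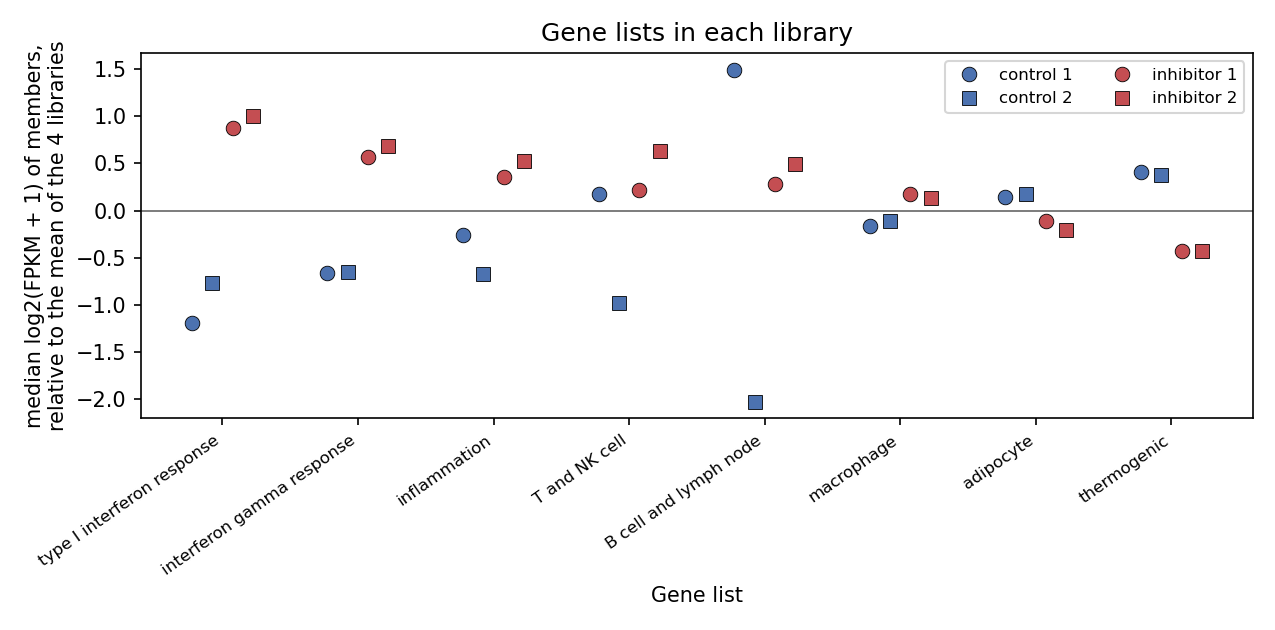
Median log2(FPKM + 1) of the members of 8 gene lists in each library, relative to each gene's mean over the 4 libraries, with circles for replicate 1 and squares for replicate 2. Both control libraries lie at -0.66 and -0.65 for the interferon gamma response, whereas for B cell and lymph node genes control 1 lies highest, control 2 lies lowest at -2.03 and the inhibitor libraries lie between them at 0.28 and 0.50.

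The comparison named by the title, browning, showed lower expression of genes of heat-producing fat in the inhibitor libraries. Of 25 measured thermogenic genes 8 fell and 0 rose, or 16 and 0 with p adjusted over the list alone, and the list median was 1.73-fold lower, a log2 fold change of -0.79. Negative log2 fold changes were seen in 24 of the 25 and a positive one in 1, and 19 had both inhibitor values below both control values. Ucp1, the uncoupling protein that releases the mitochondrial proton gradient as heat, fell from 714.8 ± 93.2 to 278.6 ± 11.7 FPKM, a log2 fold change of -1.35 ± 0.12 (adjusted p = 0.00989). It lies on chromosome 8 at 83290352 to 83298452 on the plus strand. Cidea, a lipid droplet protein of brown and beige fat on chromosome 18, fell from 194.7 ± 4.50 to 97.2 ± 4.53 FPKM. Elovl3, which elongates fatty acids, fell from 45.3 ± 1.11 to 18.3 ± 1.57 FPKM, and Cpt1b, the muscle and brown fat form of the carnitine transferase, fell from 57.8 to 25.3 FPKM. Cox7a1, a subunit of the respiratory chain, Kcnk3 and Otop1, which are ion channels, and Dio2, which activates thyroid hormone, were the others that fell, by 1.14, 0.79, 0.85 and 1.11 on the log2 scale. The regulators Ppargc1a (log2 fold change -0.97 ± 0.35, adjusted p = 0.223) and Prdm16 (-0.43 ± 0.19, adjusted p = 0.303) did not pass, although Ppargc1a passed without control 1. Camera gave an adjusted p of 2.81e-17, and adjusted p = 0.268 with an estimated correlation. Cpt1b lies within a readthrough gene on the same strand, so its reads could be shared.

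Outside the thermogenic list, 5 further genes were among the 12 with the smallest p that fell. Pck1, the enzyme that starts glyceride and glucose synthesis from oxaloacetate, fell from 718 ± 9.59 to 457.9 ± 8.82 FPKM, and Nnat, an imprinted membrane protein, fell from 304.1 to 173.0 FPKM. Phospho1, a phosphatase for phosphocholine, fell from 74.6 to 33.4 FPKM, and Abi3 from 53.7 to 27.0 FPKM. Phospho1 and Abi3 overlap by 2067 bases on opposite strands, and Nnat lies inside Blcap, so their reads may not be separate, since no source used here states whether counting used the strand. Phospho1 also lies within Zfp652 on the same strand, over 7642 bases, which counting by strand would not separate. Gm10135, which lies opposite Slain2, had 3.11 and 3.17 FPKM in the controls and was listed at 0 in both inhibitor libraries.

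Transcripts of mitochondrial oxidation were lower as lists, with few single genes past the threshold. Of 21 measured genes of fatty acid oxidation 3 fell and 0 rose, or 15 and 1 with p adjusted over the list alone, the exception being Cpt1a. The 3 calls became 8 after quantile normalization, 7 at a mean of at least 5 FPKM, 6 without mitochondrially encoded genes, 5 after upper quartile scaling, and 1 with no filter, with a replicate block and with the length and GC trend removed. The counts over the list alone became 1 and 0 without either inhibitor library, where the median of -0.40 stayed at -0.39 and -0.43. Beside Cpt1b, Acadvl, the first enzyme of very long chain oxidation, fell from 223.3 ± 14.4 to 154.7 ± 0.680 FPKM and Etfdh, which passes the electrons on to the respiratory chain, fell from 97.9 to 69.1 FPKM. Hadhb had a log2 fold change of -0.51 ± 0.09 (adjusted p = 0.0529). The median of the oxidation genes was 1.32-fold lower, with a camera adjusted p of 1.87e-14, and adjusted p = 0.268 with an estimated correlation. Without control 2 the calls for Acadvl and Etfdh ended, and without control 1 there were 5 calls. Nuclear genes of the respiratory chain gave 0 calls of 45, here and with p adjusted over the list alone, though 38 of them had both inhibitor values below both control values. Uqcrfs1 (log2 fold change -0.48, adjusted p = 0.0552), Uqcrc2 (-0.47, 0.0700), Atp5d (-0.37, 0.0759) and Atp5h (-0.35, 0.0896) were closest. Their list median was 1.19-fold lower, with a camera adjusted p of 3.44e-17, and adjusted p = 0.271 with an estimated correlation, and limma called 3 lower without control 1 and 4 after quantile normalization. Counts over the list alone depended on scaling and on the controls: 34 were lower after upper quartile scaling, 33 after quantile normalization, 29 without mitochondrially encoded genes and 14 without control 1.

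White adipocyte genes had smaller fold changes than thermogenic genes, and none passed over all genes. Of 18 adipocyte markers 0 passed over all genes and 11 were lower with p adjusted over the list alone. Those 11 became 0 without either inhibitor library and with the trend on transcript length and GC content removed, while the list median of -0.34 stayed at -0.37 without inhibitor 1, -0.29 without inhibitor 2 and -0.32 with the trend removed, and they became 7 after rescaling to a common sum, and 1 gene passed over all genes without control 1. Adipoq, which encodes adiponectin, had 1279 ± 33.6 FPKM in the controls and 1046 ± 69.2 in the inhibitor libraries, a log2 fold change of -0.29 ± 0.09 (adjusted p = 0.185). Lep, which encodes leptin, had means of 87.6 and 62.2 FPKM, -0.49 ± 0.15 on the log2 scale (adjusted p = 0.176). Slc2a4, the insulin-responsive glucose transporter, had -0.53 (adjusted p = 0.0639), and the lipid droplet genes Lipe, Plin1 and Plin4 had -0.40, -0.35 and -0.34. The list median was 1.26-fold lower, with a camera adjusted p of 3.09e-10, and adjusted p = 0.271 with an estimated correlation. Lipogenesis genes gave 0 calls of 24, or 14 lower with p adjusted over the list alone, among them Agpat2, Lpin1, Dgat2 and Gpam at -0.50, -0.47, -0.45 and -0.47. Their median was 1.36-fold lower, with a camera adjusted p of 1.96e-12, and adjusted p = 0.307 with an estimated correlation, and without control 1 limma called 13 lower. Without control 2 the median went from -0.45 to -0.29, and the 14 became 0, as they did without inhibitor 1 (median -0.45), without inhibitor 2 (-0.42), with no filter (-0.45) and with the length and GC trend removed (-0.38).

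Genes of cyclic AMP signalling, also named in the title, changed little as a list. Of 25 measured, 2 fell and 0 rose, with p adjusted over all genes and over the list alone, and 0 without either inhibitor library. Adcy3, an adenylyl cyclase that makes cyclic AMP, fell by 0.73 ± 0.11 on the log2 scale (adjusted p = 0.0346), and Pck1, a target of the pathway, was the other. Prkar2b had -0.33 and Adcy5 -0.30, neither past the threshold. The list median was -0.06, and -0.03 without control 2 and -0.04 without control 1. After upper quartile scaling it was -0.16 and after quantile normalization -0.15, where the median of all genes went from 0.07 to -0.03. Camera gave an adjusted p of 0.0194, and adjusted p = 0.271 with an estimated correlation. The list did not pass without inhibitor 1 (adjusted p = 0.105) or with the trend on transcript length and GC content removed (0.0816), and Adcy3, which overlaps Cenpo on the other strand, did not pass without control 2. Insulin and glucose genes gave 0 calls of 19, or 3 lower with p adjusted over the list alone, which became 1 without control 2 and 0 without either inhibitor library. Pdk4, which holds glucose carbon out of the citric acid cycle, had -0.68 (adjusted p = 0.0696), and passed without control 2, and Slc2a4, which passed without control 1, Pfkfb3 and Hk2 had -0.53, -0.34 and -0.32. That list's median was -0.06, and -0.18 without control 2, with a camera adjusted p of 0.0140, and adjusted p = 0.271 with an estimated correlation, and the list did not pass with the length and GC trend removed (0.0698).

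**Figure D3:**
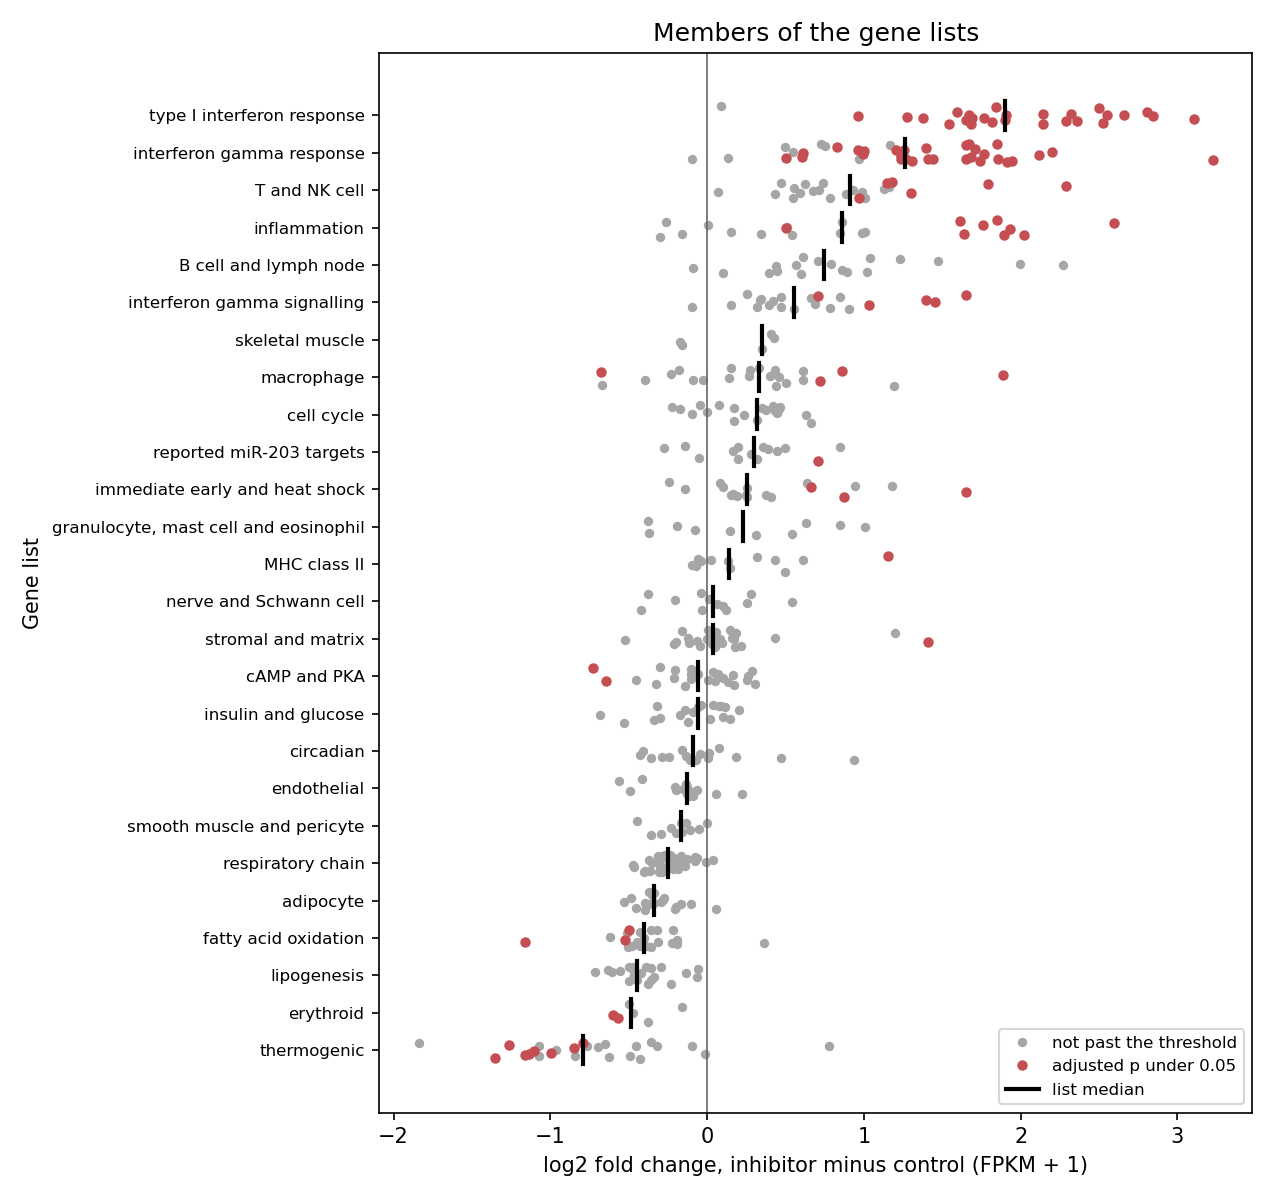
Log2 fold changes, inhibitor minus control on the scale of log2(FPKM + 1), of the measured members of 26 gene lists, with genes past an adjusted p of 0.05 in red, others in grey and list medians as black bars. The type I interferon list has the highest median, 1.90, and the thermogenic list the lowest, -0.79.

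Markers of the other cells of a fat depot were compared to describe its makeup. Endothelial markers gave 0 calls of 15, also with p adjusted over the list alone except for 2 lower without control 2, with Sox17, Cldn5, Sox18 and Cdh5 at -0.56, -0.49, -0.42 and -0.21, a median log2 fold change of -0.13, a camera adjusted p of 0.000783, and adjusted p = 0.271 with an estimated correlation. Smooth muscle and pericyte markers gave 0 calls of 11, here and with p adjusted over the list alone, with Des, Myh11, Acta2 and Notch3 at -0.45, -0.36, -0.29 and -0.23, a median of -0.17 (-0.26 without inhibitor 1), a camera adjusted p of 0.00108, and adjusted p = 0.271 with an estimated correlation. Red cell genes gave 2 calls of 6, both lower, or 4 with p adjusted over the list alone: Hba-a1 fell by 0.60 and Hba-a2 by 0.57 on the log2 scale. These are near-identical copies of alpha globin, so each value is uncertain, and neither passed without control 2. The beta globins Hbb-bt and Hbb-bs had -0.50 and -0.38, neither past the threshold. The median of the red cell list was -0.49, with a camera adjusted p of 3.39e-05, and adjusted p = 0.271 with an estimated correlation. Of 30 stromal and matrix genes Ly6a, a surface antigen of adipocyte progenitors that interferons also induce, was the 1 that rose, from 565.6 to 1492 FPKM (list camera adjusted p = 0.999). The direction of that list was unstable, with a median of 0.03 that became -0.08 without inhibitor 1, 0.14 without inhibitor 2, 0.11 without control 1 and -0.02 without control 2, and 2 genes were called without either control. Thbs1, Fn1 and Cd34 had 1.20, -0.52 and 0.16 and did not pass.

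The remaining lists had no gene past the threshold over all genes. Granulocyte, mast cell and eosinophil markers gave 0 calls of 10, or 3 higher with p adjusted over the list alone and 0 of these without either inhibitor library (adjusted p = 0.528), among them S100a8 and S100a9 at 0.85 and 1.00 (adjusted p = 0.0886 and 0.105), which passed without control 1, and Csf3r and Tpsb2 at 0.54 and -0.37. Their median was 0.23, and 0.00288 without control 2, where 1 gene passed. Nerve and Schwann cell markers gave 0 of 12, or 1 higher with p adjusted over the list alone (adjusted p = 0.791), where the median was 0.04 while camera's direction was down, and without control 1 the median was -0.10 and without control 2 0.10. Cnp, which passed without control 1, is an enzyme of myelin and had 0.54 (adjusted p = 0.0552), and Ngfr and Uchl1 had -0.38 and -0.42. Skeletal muscle genes gave 0 of 5 (adjusted p = 0.960), with Tnni2, Myl1, Tnnt3 and Tnnt1 at 0.42, -0.17, 0.41 and 0.35, and a median of 0.35 that became 0.15 without inhibitor 2 and 0.06 without control 1, with camera's direction down in both. Only 2 of 20 epithelial and mammary genes were measured, Krt19 and Trp63, neither past the threshold. Cell cycle genes gave 0 of 19, here and with p adjusted over the list alone (adjusted p = 0.104). That list passed without inhibitor 2 (0.0371), with no filter (0.0369), after upper quartile scaling (0.0366) and after quantile normalization (0.0415), with Mcm6, Tpx2, Plk1 and Cdc20 at 0.63, 0.46, 0.46 and 0.44. Circadian genes gave 0 of 16, here and with p adjusted over the list alone (adjusted p = 0.0567). They passed as a list without inhibitor 2 (0.00917), without control 1 (0.0281) and at a mean of at least 5 FPKM (0.00370), and their median of -0.09 became -0.22 without inhibitor 2, -0.03 without control 2 and 0.00168 without inhibitor 1, with Npas2, Tef, Hlf and Arntl at 0.93, -0.36, -0.43 and 0.47.

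The last comparison asked whether genes with a site for miR-203 in their 3' untranslated region were higher in the inhibitor libraries, as direct targets would be. The 7-base site CATTTCA, which pairs with bases 2 to 8 of miR-203-3p, was in 2046 of 12182 genes searched, which is 16.8%. Their mean log2 fold change was 0.10, and that of genes without the site was 0.10. The difference was -0.0013 (95% bootstrap interval -0.0174 to 0.0153), with a camera p of 0.783 and a camera direction of up, opposite in sign to the difference in means. Of the 210 words of the same base composition the site ranked 155 from the highest. The 602 genes with the longer 8-base site differed by 0.0052, with a camera p of 0.712. Among 391 genes that rose and were searched, 49 had the site, 12.5%, which is fewer than among the others in a test not fixed in advance and not matched on the length of the untranslated region (Fisher's exact test, two-sided, odds ratio 0.703, 95% interval 0.508 to 0.954, p = 0.0230). Of 30 genes that fell and were searched, 5 had the site. With the trend on length and GC content of the 3' untranslated region removed, the difference in means was -0.0047, with a camera p of 0.993. The difference in means was 0.0147 without control 2 and 0.0067 without inhibitor 1, and -0.0174 without control 1 and -0.0094 without inhibitor 2.

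Of 14 measured genes chosen in advance as reported targets of miR-203, Lyn was the 1 that rose, with p adjusted over all genes and over the list alone. With no filter, and with the length and GC trend removed, 0 of the reported targets passed over all genes and 1 over the list alone. Lyn has both the 7-base and the 8-base site, as do Abl1, Skp2, Snai2, Zfp281 and Cav1, which did not pass. The other measured targets have the 7-base site alone, except Runx2 and Smad1, which have neither. The site therefore does not set Lyn apart on this list. Outside the list, Jak1 and Ifngr1 have neither site. Socs3 had a log2 fold change of 0.85 (adjusted p = 0.120), Lasp1 0.39 (0.163) and Bmi1 0.35 (0.164), and Socs3 passed without control 1, where 3 genes were higher with p adjusted over the list alone. Their median was 1.23-fold higher, a log2 fold change of 0.30 that became 0.17 without inhibitor 2. The camera adjusted p was 0.0604, and the list passed without inhibitor 1 (0.0220), after upper quartile scaling (0.0366) and after quantile normalization (0.0365).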

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

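The alternatives without the mitochondrially encoded genes and without the length and GC trend were chosen after the results were seen. The 397 higher and 33 lower genes became 122 and 10 with no filter, where 16558 genes were tested, 215 and 11 without the trend in the variance, and 667 and 147 at a threshold of 0.1. With no filter the members called over all genes went from 26 to 15 for type I interferon, from 30 to 17 for the interferon gamma response, from 8 to 5 for the thermogenic list, and from 9 to 2 for inflammation and from 6 to 2 for T and NK cells, with list medians of 1.90, 1.26, -0.67, 0.54 and 0.88. The 397 and 33 became 323 and 45 without the mitochondrially encoded genes, and 212 and 10 with the length and GC trend removed, where the members called over all genes went from 30 to 22 for the interferon gamma response, from 8 to 5 for the thermogenic list and from 3 higher and 1 lower to 0 for the macrophage list. The medians of these lists moved little, from 1.26 to 1.25, from -0.79 to -0.72 and from 0.333 to 0.328. That fit also had no trend in the variance, and leaving out that trend alone gave the 215 and 11 above. The lost calls therefore cannot be put down to transcript length or GC content. The lower genes became 66 at a mean of at least 5 FPKM, 55 after upper quartile and 92 after quantile scaling, and the cause was not tested. Leaving out a library gave 0 to 687 higher and 0 to 98 lower genes, with fewer samples and, in the group left with 1 library, the assumption that it varies like the other. The replicate number did not pair the libraries (correlation of deviations -0.0058), and with a replicate block 333 genes were higher and 21 lower. At least 2-fold higher were 299 to 503 genes when a library was left out. At least 2-fold lower were 61 at pseudocount 0.1, 14 at a mean of at least 5 FPKM, 42 after quantile normalization and 35 to 83 when a library was left out.

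Of the gene list tests 16 passed, 0 with an estimated correlation and 6 with fry. The interferon gamma list (1.26, adjusted p = 0.268) and the thermogenic list (-0.79, adjusted p = 0.268) lost their calls with an estimated correlation, and kept direction and call in every other alternative run. The difference for genes with the site was -0.0013 with fry, which does not compare a list with other genes and gave a p of 0.0492, -0.0047 on matched genes and -0.0174 to 0.0147 when a library was left out. The log2 fold changes of 6 named genes turned without control 2. Without control 2 and without control 1 they were -0.0206 and 0.31 for H2-DMb1, -0.58 and 1.44 for H2-Oa, -1.04 and 2.27 for H2-DMb2, -0.64 and 4.63 for Glycam1, -1.08 and 5.62 for Ccl21a, and -0.30 and 0.99 for Tnnt1. The cause was not tested. Of 123 named genes 51 were called, and 0 of these changed sign in any alternative. Unknown absolute depth limits what can be said of genes near 0, such as Ifng.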

Other observations

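The gene families and all tests here were chosen after the results were seen, except the count of other splits. Beside the fixed lists, 16 gene families were tested, with p adjusted over the 16, and none kept its call with an estimated correlation. Some families share members with the fixed lists, so those genes are counted again here. Psmb8, Psmb9, Psmb10 and Parp14 are on the interferon gamma response list, Trim30a is on the type I list and Ctss is on the MHC class II list. Members of families linked to antiviral responses rose. Of 7 Schlafen genes, a family that interferons induce in immune cells, 6 rose, among them Slfn4 from 37.6 ± 14.0 to 206.7 ± 35.8 FPKM, and the family median was 1.44 on the log2 scale (camera adjusted p = 4.70e-07, and adjusted p = 0.220 with an estimated correlation). Of 12 PARP genes 5 rose, Parp9, Parp10, Parp11, Parp12 and Parp14, while 4 had negative log2 fold changes and Parp1, the DNA repair enzyme, had 21.0 and 20.4 FPKM (camera over the family, adjusted p = 0.00166, and adjusted p = 0.220 with an estimated correlation), and Parp11 did not pass without control 2. Of 12 Toll-like receptor genes 4 rose, Tlr3, Tlr7, Tlr9 and Tlr13, while Tlr8 had a log2 fold change of 0.72 (adjusted p = 0.0941) and Tlr5 -0.12 (camera over the family, adjusted p = 3.85e-05, and adjusted p = 0.249 with an estimated correlation). Of 13 MHC class I genes 6 rose, among them H2-T23 from 210.2 to 402.9 FPKM (camera over the family, adjusted p = 7.22e-07, and adjusted p = 0.220 with an estimated correlation), though these genes are near-identical and their separate values uncertain. Ifnb1, which encodes interferon beta, was listed at 0 in both controls and had 1.76 and 2.37 FPKM in the inhibitor libraries (adjusted p = 0.0273). Of 38 TRIM genes 8 rose (camera over the family, adjusted p = 0.00193, and adjusted p = 0.341 with an estimated correlation), and of 38 proteasome genes 3 rose, Psmb8, Psmb9 and Psmb10. Fc receptors (camera adjusted p = 0.0692) and collagens (0.524) did not pass as families. Fc receptors passed after upper quartile scaling (0.0482) and quantile normalization (0.0311). The families not described were cytosolic and mitochondrial ribosomes, mitochondrial carriers, V-ATPase, cathepsins and C-type lectins, with medians between -0.09 and 0.39. Each passed with camera at the preset correlation (adjusted p from 0.00166 to 0.0302). Cytosolic ribosomes and V-ATPase did not pass after upper quartile scaling (0.156 and 0.190). Among their members 2 cathepsins and 1 C-type lectin rose. Leaving out either inhibitor library, with the residual spread then taken from the controls alone, ended the calls of all these genes.

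Genes of the citric acid cycle and of the mitochondrial genome had lower values. Sdha, Sdhb, Sdhc and Sdhd, counted here with the cycle, are also on the respiratory chain list. All 18 measured genes of the cycle had both inhibitor values below both control values, 2 of them fell, among them Ogdh, whose call ended when any library was left out, and the median was 1.27-fold lower (log2 fold change -0.35, camera adjusted p = 7.93e-14, and adjusted p = 0.220 with an estimated correlation). All 13 mitochondrially encoded genes had negative log2 fold changes, with a median of -0.62 (camera adjusted p = 1.35e-11, and adjusted p = 0.249 with an estimated correlation). Of these mt-Nd1 was the 1 that fell, from 7406 to 4509 FPKM (adjusted p = 0.0497). After upper quartile scaling 0 of them passed, with a median of -0.72. Quantile normalization left 12 of the 13 negative with a median of -0.27, and limma called 12 lower without control 1 and 2 without control 2.

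The rise of the interferon-induced genes was weighed first. Lymph node tissue in the pools does not account for it, since 96.9% of 65 members were higher in both inhibitor libraries than in control 1, the library with the most lymph node signal. A larger share of otherwise unchanged macrophages would raise all their markers, but the upper quartile of these markers was 0.556, below the lower quartile of the interferon members, 1.17. The markers were mixed, with Fcgr1 at 1.89 and Cd163 at -0.68, so this comparison does not test a change in the kind or state of macrophages. Removing the trend on transcript length and GC content left the median log2 fold change at 1.63, from 1.65. The treatment itself, an innate response to a synthetic oligonucleotide, or a change in the cells that respond to interferon may be behind it, and these stay open because no test here separates them.

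The fall of the thermogenic genes was weighed next. A smaller share of adipocytes does not account for all of it, since thermogenic genes that are not adipocyte markers had a median of -0.816, below the lower quartile of the adipocyte markers, -0.370 (difference of medians -0.48, 95% bootstrap interval -0.74 to -0.28). That interval came from 10000 resamples of genes, which are not independent replicates, so it does not measure the spread between pools. Scaling does not account for the fall either, since the highest median over 4 scalings was -0.769. Whether fewer heat-producing adipocytes or lower expression in each of them may be the cause is untested, and so is the effect of the treatment.

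B cell and lymph node genes were low in control 2, with a median log2 ratio of control 2 to control 1 of -3.49 over 18 markers, or 11.2-fold lower, against -0.157 to 0.077 for 95% of random sets of matched abundance. That ratio measures the size of the pattern and does not test an explanation of it. The median ratio of 3223 other genes of matched abundance was -0.0356, which cannot test depth, since FPKM values are divided by library size. The most common ratio of low values put the depth of control 2 at 1.05 relative to control 1. Only ratios near equal depth were used, so a much shallower library could not have been found and depth stays open. Less lymph node tissue in that pool could be the reason but stays untested, and Cxcl13, a lymph node chemokine with 60.3 FPKM in control 1 and 58.2 in control 2, goes against it, while Cd79a, a B cell receptor chain, had 66.2 and 0.636. A difference between animals is open, so T cell, B cell and MHC class II values of the controls should be read per library.

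Of the 3 ways to split the 4 libraries into 2 pairs, 1 gave as many called genes as the real split, which is the real split itself with 430, and the highest other gave 0. With 3 splits no share under 0.05 can be reached.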
